A study of Arabidopsis thaliana with 40 samples.

How the data were processed

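The series measured mRNA of whole Arabidopsis thaliana seedlings, 9 days old, that were kept for 3 h in the dark or for 3 h under water in the dark. Total mRNA and RNA from heavy polysomes (mRNA carrying many ribosomes) were sequenced on an Illumina HiSeq 2000, per the labels' protocols. The 40 samples belong to 2 experiments. The first holds 16 libraries in 8 groups of 2: the wild type Col-0 and the line K48M, in which the SnRK1 catalytic subunit KIN10 is overexpressed in Col-0 with the K48M amino acid change, each as total and polysome RNA in the dark and under submergence. The second holds 24 samples in 12 groups of 2, with Col-0 and the lines i4g1-2 and 4A-15 in the same fractions and conditions. Per the series text the repeats are independent biological ones. The p-values given here measure only the spread between these libraries.

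For the first experiment the authors deposited whole-number read counts per transcript model for each library, as total and as unique gene reads, made from trimmed read pairs, per the file headers. The build was TAIR10, per the submitters' processing notes; the aligner and the library kit's strandedness are not given in the sources used here. The same count tables carry the authors' own test, called EDGE in the file headers, with a signed fold change stored as a score and an FDR-corrected p-value per model. A second workbook holds the authors' log2 fold changes of submergence against dark for 4 genotypes and both fractions, together with gene lists and a translational status score that the authors deposited without a stated formula or log base. The status changes given here are the submergence value minus the control value. For each Col-0 group the authors' index in this workbook lists 1 library of the first experiment and 2 with names of the second, and for K48M the 4 libraries of the first experiment in each fraction. For Col-0 total dark, 1 of the 2 listed names belongs by title to a Col-0 polysome library, so which library was meant is open. Counts of the second experiment were not analysed here, so i4g1-2 and 4A-15 are described by the authors' folds alone, without an error or a test. The planned tests of that experiment were therefore not run.

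Counts of 41660 transcript models were summed to 33592 genes, of which 32825 matched a row of the reference annotation (assembly TAIR10.1) by locus code. Each table has 11 rows whose identifiers were removed before this work, holding at most 0.0084% of a library's reads, and these were left out. Gene reads per library ran from 5.26 to 6.77 M in total mRNA and from 3.75 to 5.95 M in polysome RNA. The authors' index gives 28.8 to 56.0 M reads for 35 libraries of the series. Reads matching a single model made up 54.4% to 73.0% of the gene reads, so genes with close copies, several overlapping models or an antisense partner have uncertain counts. The 15 annotated ribosomal RNA genes took between 0.87% and 38.12% of the gene reads of a library.

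The condition of 2 libraries is in conflict. The sample titles call one library of the LTF_GG set K48M total dark and another K48M total submerged, while the column headers and the authors' index give the opposite conditions. Both were left out of the comparisons, which used 14 of the 16 libraries that the design named. This choice was made after values of single libraries had been seen. The K48M total groups then hold 1 library each, from the ST_FR set, and are assumed to vary like the other groups. Fits of all 16 libraries with the conditions of the headers, or of the titles, were run as alternatives.

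Genes were tested with edgeR 4.0.16 in R 4.3.3. All groups entered 1 quasi-likelihood model (glmQLFit and glmQLFTest) with TMM scaling, a term per group and an additive term for the library set, with 5 residual degrees of freedom. The filter for low counts (filterByExpr, minimum count 10 and minimum total 15) left 19024 genes. P-values were adjusted by Benjamini-Hochberg over these genes, and an adjusted p under 0.05 counted as a call. The biological coefficient of variation was 18.8%, and the TMM factors ran from 0.558 to 1.311. Contrasts gave the submergence response of each genotype in each fraction, the difference of the responses (K48M minus Col-0), K48M against Col-0 in the dark, and the change of polysome loading, defined as the polysome response minus the total response. TMM scaling assumes that most genes do not change, so a shift shared by most mRNAs, such as fewer mRNAs on polysomes, is removed from each contrast. Standard errors were computed as the absolute log2 fold change divided by the root of the F statistic and are not printed for folds near 0. CPM values (read counts relative to library size) are given after TMM scaling.

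The 2 library sets, ST_FR and LTF_GG, each hold 1 library of every group, and the set number served as the replicate block. Libraries of the same set deviated together from their group means in each of the 15 pairs of groups, with r across 14670 genes between 0.35 and 0.74 (median 0.58). Replicates of the 6 groups with undisputed labels correlated with r between 0.926 and 0.958 across genes and differed by far more than sampling noise (chi-square per gene 26.8 to 137.3), so none was counted as a duplicate. The authors' index numbers batches in another way: within the LTF_GG set it calls Col-0 polysome dark and all K48M libraries batch 1, but Col-0 total and Col-0 polysome submerged batch 3, and it does not list the Col-0 libraries of the ST_FR set. Whether these numbers count days or only repeats within a group is not given in the sources used here, so the Col-0 polysome pair of the LTF_GG set may cross batches, although its dark and submerged libraries deviated together (r = 0.63). The first principal components held 35.5%, 21.3% and 16.7% of the variance. On the third the ST_FR libraries lay between −43.51 and 2.63 and the undisputed LTF_GG libraries between 19.94 and 53.18. The LTF_GG pair in conflict lay at −14.17 and −2.35 there, and stood apart on the fourth at −41.28 and −40.04. This pair thus did not share the deviation of its set, so the set term describes it poorly in the fits of 16 libraries.

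The groups, the model, 15 gene lists, the rule for naming genes and the alternatives other than those named as added were fixed before the data were examined. The lists cover core hypoxia genes, fermentation and sucrose breakdown, heat shock, starvation genes under SnRK1, the SnRK1 complex, group VII ethylene response factors (ERF-VII), ethylene, jasmonate and touch, abscisic acid, the circadian clock, photosynthesis, translation initiation, cytosolic ribosomal proteins by description, plastid and mitochondrial genomes (their ribosomal RNA genes included), and root markers. The list of cytosolic ribosomal proteins by description had only 6 measured members of 22, so 1 list was added after that was seen: the genes that the reference annotation's notes call cytosolic ribosomal proteins, 194 of them measured. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 15 fixed lists, and again with an estimated correlation; the p of the added list is unadjusted. Counts adjusted over the list alone are given beside those over all genes. Named genes are the targets KIN10 and eIFiso4G1, then per comparison the 10 called genes that rose most and the 10 that fell most with a mean of at least 5 CPM and the same direction in each library set compared, and up to 4 members of each list with the smallest p (all members of a list with fewer than 6 measured). From the authors' folds, the 5 largest and 5 smallest per column and list members are named. A fold against a group without reads is given as a lower bound, computed with a floor of 3 counts over the group, which covers counting error only. Groups with a few reads were fitted without this floor. The largest folds, such as those of HSP21 and ATHSP22.0, rest on dark levels near it, so their size is uncertain.

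Alternatives were size factors of the DESeq2 type (RLE) in place of TMM, the test of DESeq2 1.42.0, no filter on low counts (24762 genes), each library left out in turn, no replicate block, and a block by library set within each fraction. Added after the data were seen were the fits of 16 libraries, unique gene reads (16529 genes) and a fit without the ribosomal RNA genes. Counts were also simulated for the 14 libraries from the fitted dispersions, with 100 genes changed 2-fold and 100 changed 4-fold in 1 group. For the Col-0 total response the test called 18% of the former and 85% of the latter, and 97.4% of the latter with at least 5 CPM. For the difference of responses the shares at 4-fold were 22% in total and 55% in polysome RNA, for K48M total 62%, for Col-0 loading 46%, and for K48M against Col-0 polysomes in the dark 79%. False calls made up 4.6% to 21.4% of all calls in these simulations, above the nominal level in all but the Col-0 total response. Of the unchanged simulated genes 4.6% to 5% had an unadjusted p under 0.05. The real libraries gave 2.6% for the total difference, 1.3% for the polysome difference, 1.5% for Col-0 loading and 1.6% for polysomes in the dark. The recovery shares may therefore not hold for the real libraries in these comparisons. Camera, tested on simulated data, called a raised list (adjusted p = 7.12e-17, and 0.00335 with an estimated correlation) and 0 of the unchanged lists. The simulated genes were drawn independently of each other. This check therefore could not show whether the preset correlation holds for lists of genes that vary together. Overlap with the authors' calls was tested with a one-sided Fisher's exact test (scipy 1.17.1). Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.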

Results

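KIN10 is the catalytic subunit of the kinase SnRK1, and the K48M line overexpresses it with the K48M amino acid change. Kinase activity was not measured here, so a higher KIN10 mRNA level in K48M does not show a gain of SnRK1 function. KIN10 ran from 27 to 37.6 CPM in the Col-0 total libraries and from 28.5 to 31.2 CPM in the Col-0 polysome libraries. In K48M it ran from 1200 to 1550 CPM in total mRNA and from 242 to 419 CPM in polysome RNA. In the dark it was higher in K48M than in Col-0 by a log2 fold change of 5.25 ± 0.26 (standard error here and below) in total mRNA (1 library against 2, edgeR quasi-likelihood, BH-adjusted p = 3.43e-07) and of 3.00 ± 0.22 in polysome RNA (2 against 2, adjusted p = 6.18e-05). In Col-0 total mRNA KIN10 was at 33.2 ± 6.24 CPM in the dark and 30 ± 4.21 CPM under submergence (mean ± SD, n = 2). In K48M polysome RNA, KIN10 was at 245 ± 4.55 CPM in the dark and 406 ± 18 CPM under submergence (log2 0.73 ± 0.20, adjusted p = 0.0261), a call that each left-out K48M polysome library ended (adjusted p = 0.133 and 0.193 without the dark libraries, 0.16 and 0.101 without the submerged ones) and that was absent without the replicate block (0.27).

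eIFiso4G1, a scaffold subunit of the translation initiation factor eIFiso4F, was measured in every library, at 67.4 to 104 CPM in Col-0 total, 63.5 to 74.6 CPM in Col-0 polysome, 67.1 to 103 CPM in K48M total and 48.5 to 69.2 CPM in K48M polysome RNA. It was not called in any comparison. Its log2 responses to submergence were −0.19 ± 0.21 in Col-0 total (adjusted p = 0.631), 0.51 ± 0.30 in K48M total (0.382) and 0.33 ± 0.22 in K48M polysome RNA (0.367). In the dark its K48M against Col-0 value was −0.38 ± 0.27 in total mRNA (adjusted p = 0.692) and −0.42 ± 0.22 in polysome RNA (adjusted p = 1).

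**Figure D1:**
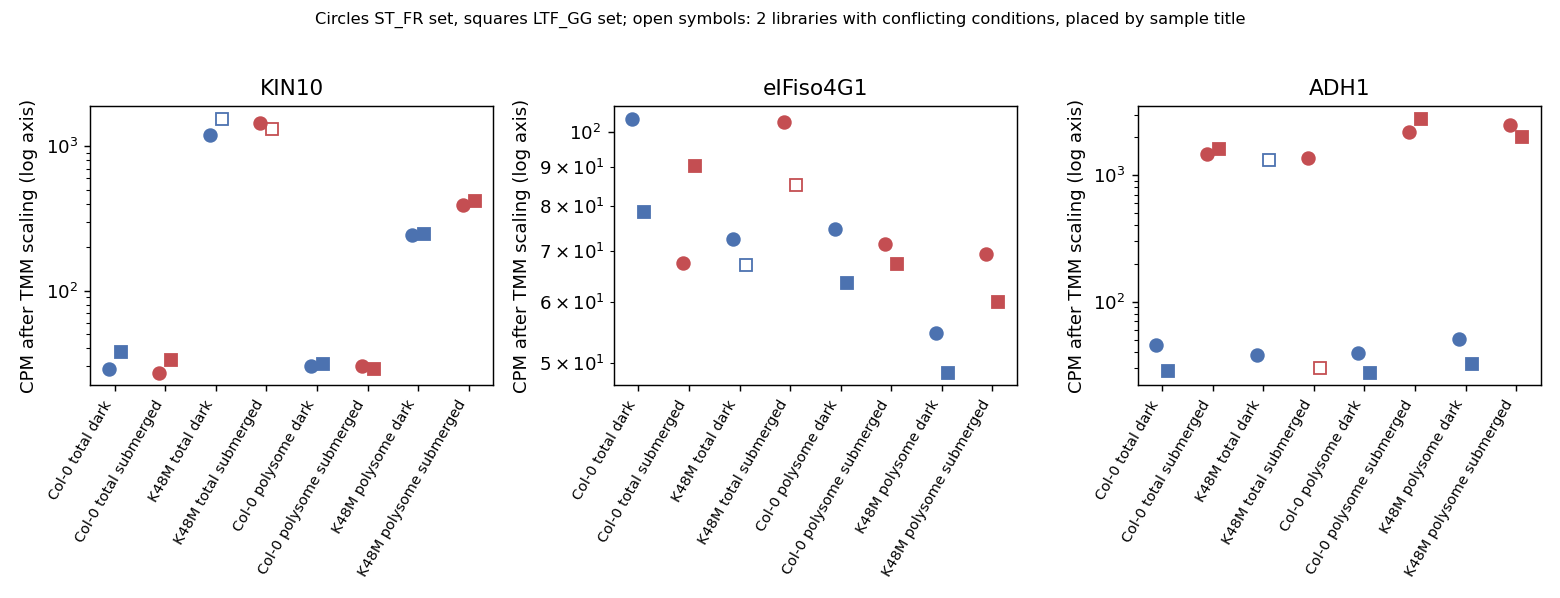
KIN10, eIFiso4G1 and ADH1 in each of the 16 libraries, in CPM on a log axis (circles, ST_FR set; squares, LTF_GG set; blue, dark; red, submerged; open symbols, the 2 libraries in conflict, placed by title). KIN10 reaches 1200 to 1550 CPM in K48M total mRNA against 27 to 37.6 CPM in Col-0 total mRNA.

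In Col-0 total mRNA, 3 h of submergence raised the genes of fermentation and of sucrose breakdown together with the core hypoxia genes. ADH1, the alcohol dehydrogenase of ethanol fermentation, went from 36.8 ± 12.1 to 1540 ± 116 CPM (n = 2 each, log2 5.42 ± 0.33, adjusted p = 6.97e-07). PDC1, a pyruvate decarboxylase, rose by 5.99 ± 0.50, and the sucrose synthases SUS4 and SUS1 by 5.63 ± 0.33 and 4.36 ± 0.31. CML38, a calmodulin-like protein, rose from 3.20 ± 1.13 to 178 ± 50.9 CPM (5.79 ± 0.26) and the aquaporin NIP2;1 from 0.321 ± 0.211 to 107 ± 43.3 CPM (8.27 ± 0.54). Of the 47 core hypoxia genes 46 rose, also when adjusted over the list alone (median log2 4.00, camera adjusted p = 7.45e-56), and of 13 measured fermentation and sucrose genes 10 rose (10 up and 1 down over the list alone; adjusted p = 9.71e-11).

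Heat shock genes rose with them although the labels name no heat treatment. The small heat shock proteins HSP21 of the plastid and ATHSP22.0 of the endoplasmic reticulum rose by 8.31 ± 0.64 and 7.06 ± 0.47, HSP23.6-MITO by 5.15 ± 0.41 and the cytosolic HSP17.6II by 3.96 ± 0.29, and 17 of the 18 listed genes rose (18 over the list alone; median 2.95, or 2.66 with the 1 gene without dark reads at its bound; adjusted p = 4.57e-19). Among ethylene genes the biosynthesis enzyme ACO1 and the receptor ETR2 rose by 4.05 ± 0.29 and 2.99 ± 0.40, and 4 of 19 rose (6 up and 1 down over the list alone; adjusted p = 0.0187, and 0.364 with an estimated correlation). The factors ERF71 and ERF73 rose by 5.83 ± 0.38 and 3.39 ± 0.22, with 3 of 5 members of their ERF-VII family raised (adjusted p = 0.00119, and 0.103 with an estimated correlation). CYP707A3, which breaks down abscisic acid, rose by 3.70 ± 0.45, while the abscisic acid list had 2 members up and 3 down of 12 (3 and 6 over the list alone, camera adjusted p = 0.577). In the edgeR fit of 16 libraries with the header conditions, some of these calls ended. They were ACS7 (adjusted p = 0.0555) and EBF2 (0.228) among ethylene genes, RAP2.2 (0.0675) of the ERF-VII family and RAB18 (0.0673) of the abscisic acid list. Single left-out libraries ended calls in these lists too. Those of RAP2.2 and EBF2 ended without either dark library or without the first submerged one. Those of RAB18 and COR15A ended without either dark library or without the second submerged one. Those of ACS7 and NCED3 ended without the second dark library. Of 25 starvation genes 11 rose (16 over the list alone; median 0.96, adjusted p = 8.79e-08, and 0.101 with an estimated correlation), among them ERD5, a proline dehydrogenase (1.73 ± 0.26).

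IAA29, XTH6, LTL1, CYP71A16 and CYP705A5 were among the genes that fell most in Col-0 total mRNA. IAA29, an auxin response repressor, fell from 24.5 ± 9.14 to 1.28 ± 0.0806 CPM (n = 2, log2 −4.27 ± 0.34, adjusted p = 5.46e-06), the cell wall enzyme XTH6 from 59.5 ± 8.98 to 6.56 ± 3.04 CPM (−3.23 ± 0.38), and the lipase LTL1 by −2.91 ± 0.32. The root-expressed cytochrome P450 genes CYP71A16 and CYP705A5 fell by −3.52 ± 0.46 and −3.20 ± 0.49, and the expansin gene EXPA10 rose by 3.03 ± 0.42. The ribosomal protein genes RPL3B and AT2G32220 fell by −1.90 ± 0.27 and −1.51 ± 0.25. In all 1447 genes rose and 897 fell of 19024. Without the first or the second dark library the calls were 966 and 977, and in the fit without the replicate block 471. Of the genes named here HSP23.6-MITO (adjusted p = 0.091), HSP17.6II (0.11), ERD5 (0.573), RPL3B (0.118) and AT2G32220 (0.409) had no call without that block.

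In K48M total mRNA the same hypoxia and heat shock lists rose, from 1 library per condition. CML38 was higher by a log2 of 5.91 ± 0.37 (adjusted p = 7.01e-06), ADH1 by 5.19 ± 0.46, SUS4 by 5.11 ± 0.48, SUS1 by 3.54 ± 0.43 and ACO1 by 3.80 ± 0.41. Of the 47 core hypoxia genes 44 rose (46 up and 1 down over the list alone; median 3.57, adjusted p = 9.26e-49), as did 9 of 13 fermentation genes (10 over the list alone; adjusted p = 6.75e-11). Of the 18 heat shock genes 17 rose (18 over the list alone; median 3.82, adjusted p = 3.29e-23), with ATHSP22.0 at 8.23 ± 0.61, HSP21 at 8.06 ± 0.69 and HSP17.6II at 5.61 ± 0.44. ERF71 and ERF73 rose by 5.85 ± 0.52 and 3.61 ± 0.32, and the alanine aminotransferase AlaAT1 by 2.67 ± 0.34. Of the 25 starvation genes 8 rose (19 over the list alone; median 1.33, adjusted p = 8.3e-10, and 0.0842 with an estimated correlation), with ERD5 at 2.06 ± 0.37. LTL1 fell by −4.50 ± 0.48, the lipase-like AT4G28780 by −3.84 ± 0.47 and XTH6 by −3.67 ± 0.54. In all 648 genes rose and 356 fell. In the fit without the replicate block 54 genes were called, without HSP21 (adjusted p = 0.227), ATHSP22.0 (0.118), HSP17.6II (0.317), ERF71 (0.17), ERF73 (0.208), AlaAT1 (0.0585), ERD5 (0.785) and XTH6 (0.0929). On unique gene reads CML38 had no call (0.0595).

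The K48M total result rests on the ST_FR libraries, because the conditions of the LTF_GG pair conflict. With this pair added under the conditions of the column headers, ADH1 was higher by 5.33 (adjusted p = 1.89e-06), CML38 by 5.99, HSP17.6II by 5.42 and ERD5 by 2.00. Other values moved further: ATHSP22.0 from 8.23 to 6.59, SUS4 from 5.11 to 5.86, AT4G28780 from −3.84 to −2.57, XTH6 from −3.67 to −2.93 and LTL1 from −4.50 to −3.89. The 16-library fit then called 1653 genes in K48M total mRNA, 1475 in Col-0 total, 1212 in Col-0 polysome and 1567 in K48M polysome RNA. With the pair under the conditions of the titles, ADH1 in K48M total mRNA was at −0.24, SUS4 at −0.67 and ERF73 at −0.08, and edgeR called 0 genes in each of the 4 responses.

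In total mRNA the response of HSP17.6II was larger in K48M than in Col-0 by a log2 of 1.65 ± 0.56 (1.48 with the header conditions), that of AT2G44860 by 1.13 ± 0.35 (0.55) and that of the coactivator MBF1C by 0.90 ± 0.37 (0.40), none of which passed the adjustment (adjusted p = 1 for each). Over the heat shock list the difference was positive in 13 of 18 genes, with a median of 0.73 (camera adjusted p = 8.71e-06, and 0.0913 with an estimated correlation). The hypoxia list had a negative difference in 35 of 47 genes (median −0.42, adjusted p = 0.00638, and 0.758 with an estimated correlation). edgeR called 0 genes (487 at an unadjusted p under 0.05), and DESeq2 called 1, AT1G48598 (−2.56, adjusted p = 0.0186), which was singled out after its value was seen. In simulated data the test recovered 22% of genes that differed 4-fold, so smaller differences would mostly be missed there. The 487 genes are 2.6% of those tested, against 4.6% of the unchanged simulated genes at such a p. The test was thus stricter on the real libraries, and the power behind the 0 edgeR calls is not known.

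In Col-0 polysome RNA, the fermentation and hypoxia mRNAs rose as well. ADH1 went from 33.3 ± 8.34 to 2480 ± 427 CPM (n = 2 each, log2 6.26 ± 0.35, adjusted p = 5.43e-07), CML38 rose by 6.36 ± 0.30, PDC1 by 6.22 ± 0.52, SUS4 by 5.87 ± 0.34, SUS1 by 4.50 ± 0.32 and AlaAT1 by 3.03 ± 0.24. NIP2;1 had no reads in the dark libraries and was at least 376-fold higher under submergence. Of the 47 core hypoxia genes 46 rose, also over the list alone (median 4.04, adjusted p = 5.47e-53), and 10 of 13 fermentation genes (10 up and 1 down over the list alone; adjusted p = 7.87e-11). ERF71 rose by 6.26 ± 0.40, ERF73 by 3.66 ± 0.22, ACO1 by 4.01 ± 0.29 and ETR2 by 3.01 ± 0.41. Of the heat shock genes 16 of 18 rose (18 over the list alone; median 2.90, or 2.48 with that gene at its bound; adjusted p = 1.32e-17), with HSP21 at 7.67 ± 0.66, ATHSP22.0 at 7.36 ± 0.53 and HSP17.6II at 4.36 ± 0.31. Of the starvation genes 14 of 25 rose (18 over the list alone; median 1.01, adjusted p = 2.74e-09, and 0.0771 with an estimated correlation), among them ERD5 (1.58 ± 0.26) and the raffinose synthase family gene DIN10 (1.69 ± 0.27).

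In Col-0 polysome RNA, IAA29 fell by −4.20 ± 0.33, XTH6 from 51.3 ± 23.1 to 4.59 ± 2.39 CPM (log2 −3.48 ± 0.40) and the annexin ANNAT4 from 40 ± 10.6 to 4.6 ± 0.602 CPM (−3.11 ± 0.29; n = 2). Of the 194 ribosomal protein genes of the added list 53 fell (84 over the list alone; 0 of the 53 kept the call without the replicate block), 187 had a negative value and the median was −0.56 (camera unadjusted p = 1.18e-21, and p = 0.0347 with an estimated correlation), among them RPL3B (−1.63 ± 0.26) and AT2G32220 (−1.48 ± 0.22). The ribosomal RNA genes took 38.12% and 2.34% of the gene reads in the dark libraries and 2.2% and 3.87% in the submerged ones, and organelle genes moved with this share (median −1.74, 0 of 89 called, 0 over the list alone; adjusted p = 7.09e-06, and 0.634 with an estimated correlation); without the first dark library their median was 0.19, with 33 of 89 negative. In all 1228 genes rose and 865 fell. The calls were 1182 and 981 without the first or second dark library and 883 and 715 without the first or second submerged one. In the fit without the replicate block, whose LTF_GG pair here carries different batch numbers in the authors' index, they were 369, without HSP21 (adjusted p = 0.0598), HSP17.6II (0.105), ERD5 (0.657), DIN10 (0.451), RPL3B (0.219) and AT2G32220 (0.401), and on unique gene reads CML38 (0.0927) and DIN10 (0.352) had no call.

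In K48M polysome RNA, hypoxia, fermentation and heat shock mRNAs rose together. ADH1 went from 41.5 ± 13.1 to 2240 ± 323 CPM (n = 2 each, log2 5.77 ± 0.34), PDC1 rose by 6.47 ± 0.52, CML38 by 6.25 ± 0.29, SUS4 by 5.33 ± 0.32, SUS1 by 4.05 ± 0.31 and NIP2;1 by 7.70 ± 0.57. Of the 47 core hypoxia genes 46 rose, also over the list alone (median 3.61, adjusted p = 6.9e-48), and 10 of 13 fermentation genes (10 up and 1 down over the list alone; adjusted p = 2.77e-10). ATHSP22.0 rose by 8.42 ± 0.50 (adjusted p = 6.22e-07), HSP23.6-MITO by 7.34 ± 0.52 and HSP17.6II by 6.29 ± 0.33, with 17 of 18 heat shock genes raised (18 over the list alone; median 3.27, adjusted p = 6.9e-20). Of the starvation genes 18 of 25 rose (21 over the list alone; median 1.2, adjusted p = 3.9e-11, and 0.0695 with an estimated correlation), among them ERD5 (2.19 ± 0.27), DIN10 (1.68 ± 0.27), the branched-chain keto acid dehydrogenase gene BCE2 (1.57 ± 0.22) and the trehalose phosphate synthase family gene TPS8 (1.33 ± 0.22).

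In K48M polysome RNA 11 of 26 photosynthesis genes fell, among them LHCB2.3, a light-harvesting protein of photosystem II (495 ± 347 to 83.4 ± 2.23 CPM, n = 2, log2 −2.35 ± 0.40; list: 11 over the list alone; 0 of the 11 kept without the replicate block; median −0.73, adjusted p = 5.36e-08, and 0.178 with an estimated correlation). Of the 194 ribosomal protein genes of the added list 106 fell (156 over the list alone; 0 of the 106 kept the call without the replicate block) and all 194 had a negative value (median −0.77; camera unadjusted p = 2.88e-31, and p = 0.0172 with an estimated correlation), with RPL3B at −1.94 ± 0.26 and AT3G44590 at −1.53 ± 0.20. ANNAT4 fell by −3.82 ± 0.32, PRE1, a growth-promoting helix-loop-helix gene, by −4.15 ± 0.50 and CYP71A16 by −3.98 ± 0.48. In all 1470 genes rose and 1183 fell. The calls were 1088 and 920 without the first or second dark library and 969 and 1390 without the first or second submerged one. In the fit without the replicate block they were 509, and HSP23.6-MITO (adjusted p = 0.0568), ERD5 (0.44), DIN10 (0.383), BCE2 (0.357), TPS8 (0.227), LHCB2.3 (0.0718), RPL3B (0.119) and AT3G44590 (0.32) had no call, nor did CML38 (0.0715), DIN10 (0.278) and BCE2 (0.763) on unique gene reads.

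**Figure D2:**
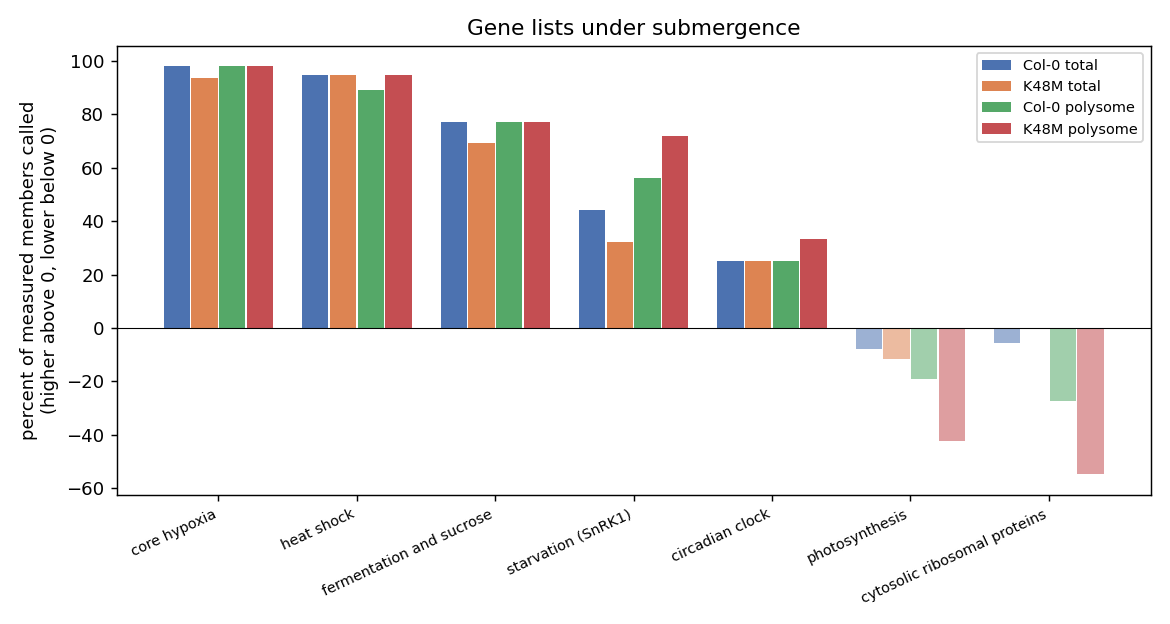
Percent of measured members of 7 gene lists called higher (above 0) or lower (below 0) under submergence in each of the 4 responses. Of the 47 core hypoxia genes 46, 44, 46 and 46 were called higher in Col-0 total, K48M total, Col-0 polysome and K48M polysome RNA.

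The replicate block bears on the list calls to different degrees. Without it hypoxia genes kept 40, 15, 38 and 38 of their 46, 44, 46 and 46 calls in Col-0 total, K48M total, Col-0 polysome and K48M polysome RNA, and fermentation genes 9, 4, 9 and 9. Heat shock genes kept 2, 0, 1 and 3 and starvation genes 1, 0, 0 and 0, while photosynthesis and ribosomal protein genes of the added list kept 0 in each response. With the header conditions heat shock genes kept 16, 16, 14 and 16 calls, starvation genes 6, 7, 11 and 14, photosynthesis genes 0, 0, 0 and 2, and ribosomal protein genes 3, 1, 2 and 10. Without the first dark, second dark, first submerged or second submerged library, starvation genes kept 3, 6, 9 and 9 calls in Col-0 total, 7, 6, 6 and 5 in Col-0 polysome and 7, 8, 9 and 13 in K48M polysome RNA. In the same order photosynthesis genes kept 0, 0, 1 and 2, then 1, 3, 0 and 2, then 3, 2, 1 and 5, and ribosomal protein genes 3, 3, 7 and 7, then 11, 17, 6 and 2, then 31, 12, 12 and 28.

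The responses of the genotypes and fractions were correlated across genes. Between Col-0 and K48M the log2 responses correlated with r = 0.74 in total mRNA and r = 0.79 in polysome RNA. In polysome RNA 998 genes were called higher in both genotypes where independent calls would give 94.9, and 630 lower where they would give 53.8. In total mRNA the shared calls were 576 (49.3) and 261 (16.8). Between total and polysome RNA, Col-0 shared 1001 higher (93.4) and 507 lower genes (40.8), with r = 0.83. No gene was called in opposite directions in any of these pairs. At an FDR under 0.05 the authors' own test on these counts called far fewer of the genes measured here. It called 243 higher and 39 lower in Col-0 total, 181 and 23 in Col-0 polysome and 316 and 76 in K48M polysome RNA. Of these 242 and 39, 181 and 23, and 314 and 73 were called here too (one-sided Fisher's exact test, p at most 1.01e-31). For these responses both tests used the same libraries, so this overlap is not independent evidence. K48M total mRNA is left out of these counts, because the authors' test there also used the LTF_GG pair in conflict. The overlap was lower there.

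In polysome RNA the difference of the responses, K48M minus Col-0, was 1.94 ± 0.52 for HSP17.6II, 3.10 ± 0.89 for the dehydrin RAB18, 2.62 ± 0.86 for HSP23.6-MITO and 0.79 ± 0.29 for KIN10, and none passed the adjustment (2 libraries per group, adjusted p = 1 for each). In the dark HSP23.6-MITO and HSP17.6II were at −1.80 ± 0.80 and −1.07 ± 0.47 in K48M against Col-0, at low means of 1.77 and 2.68 CPM. These lower dark values make up part of both differences. The heat shock list was positive in 15 of 18 genes (median 0.65, camera adjusted p = 1.44e-06, and 0.0769 with an estimated correlation; 0.0523 without the replicate block). Photosynthesis genes were negative in 26 of 26 (median −0.33, adjusted p = 9.86e-05, and 0.687 with an estimated correlation). The ribosomal protein genes were negative in 177 of 194 (median −0.20, unadjusted p = 2.02e-07, and p = 0.179 with an estimated correlation). The hypoxia list had a median of −0.29 (adjusted p = 0.0601). edgeR and DESeq2 called 0 genes. In edgeR 241 genes, 1.3% of those tested, had an unadjusted p under 0.05. The test recovered 55% of simulated 4-fold differences, but 5% of the unchanged simulated genes had such a p. The test was thus stricter on the real libraries than on the simulated ones, and the power behind the 0 calls is not known.

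Between K48M and Col-0 in the dark, KIN10 was the 1 gene that edgeR called in each fraction. In total mRNA the starvation list stood at a median of −0.26 (camera adjusted p = 0.269), the heat shock list had an adjusted p of 0.176, and BCE2 a value of −0.90 ± 0.29 (adjusted p = 0.436; 1 K48M library against 2). In polysome RNA HSP17.6II was at −1.07 ± 0.47 and VSP2, a jasmonate-induced storage protein gene, at −0.80 ± 0.32 (adjusted p = 1 for each). Organelle genes were lower in K48M in 88 of 89 cases (median −1.70, adjusted p = 9.16e-18, and 0.802 with an estimated correlation), but without the first Col-0 polysome dark library the median was 0.16, with 34 of 89 negative. The root markers were negative in 12 of 13 (median −0.25, adjusted p = 0.0419, and 0.692 with an estimated correlation; 0.0845 without the replicate block). At an unadjusted p under 0.05 edgeR counted 1781 genes in total and 310 in polysome RNA, and DESeq2 called 13 and 1. On unique gene reads 0 genes were called, where KIN10 itself keeps 0 to 7 reads per library.

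**Figure D3:**
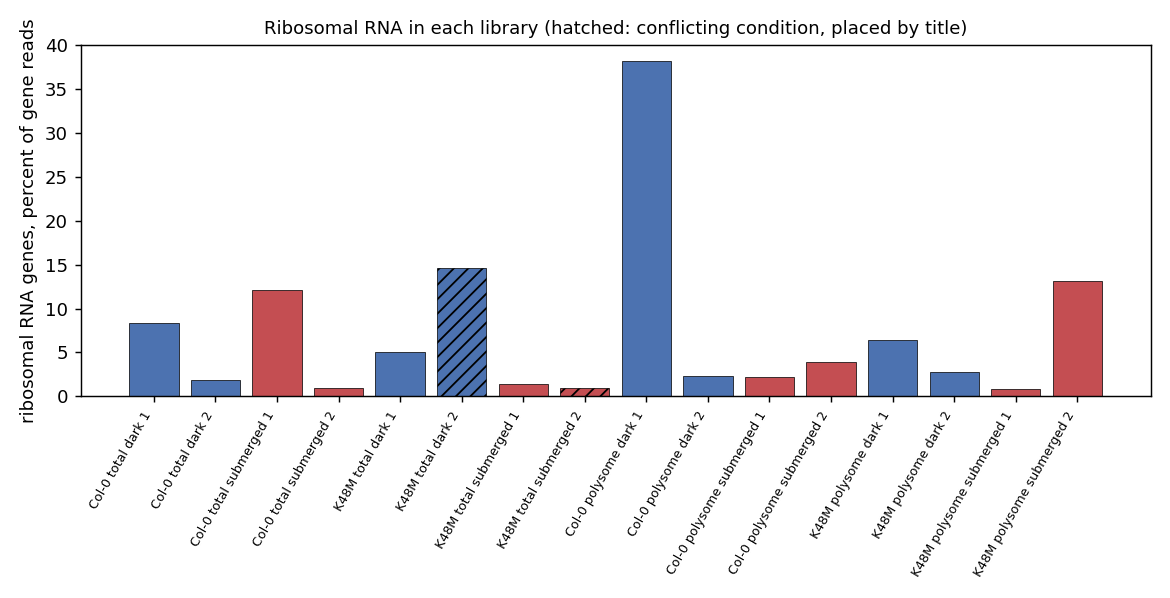
Share of gene reads from ribosomal RNA genes in each of the 16 libraries, in percent (hatched, the 2 libraries in conflict, placed by title). The first Col-0 polysome dark library stands apart at 38.12%, against 2.34% in its replicate.

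The change of polysome loading, the polysome response minus the total response, was negative for most ribosomal protein genes. In Col-0 it was negative for 170 of 194 (median −0.29, camera unadjusted p = 5.87e-15, and p = 0.0656 with an estimated correlation), with EMB1080 at −1.15 ± 0.33 and AT5G47700 at −1.28 ± 0.38 (adjusted p = 1 for both). In K48M it was negative for 179 of 194 (median −0.56, p = 3.68e-25, and p = 0.0263 with an estimated correlation), with AT5G02610 at −1.45 ± 0.33 (adjusted p = 1) from 1 total library per condition. The difference between the genotypes was negative for 138 of 194 (median −0.19, p = 8.7e-05, and p = 0.291 with an estimated correlation). ADH1 had a loading change of 0.84 ± 0.40 in Col-0 (adjusted p = 1). edgeR called 0 genes in Col-0, in K48M and in their difference (285, 559 and 298 at an unadjusted p under 0.05), and DESeq2 called 0 in each. A loading change shared by most mRNAs is removed by the scaling and could not be called. Without the second Col-0 total submerged library 1 gene was called in Col-0, TPX2 (−2.74, adjusted p = 0.0127), singled out after its value was seen.

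The lines of the second experiment are described by the authors' deposited table of log2 folds for 8391 models. In total mRNA of the authors' deposited table, ADH1 stood at 5.86 in Col-0, 5.35 in K48M, 5.53 in i4g1-2 and 5.78 in 4A-15, and SUS4 at 5.64, 5.83, 5.43 and 5.51. In the polysome columns of the authors' deposited table ADH1 stood at 6.01, 4.74, 5.01 and 5.21, and PDC1 at 6.55, 5.25, 5.61 and 5.64. The median of the core hypoxia list in total mRNA of the authors' deposited table was 3.94, 3.96, 3.82 and 4.19, and in its polysome columns 3.82, 2.18, 3.05 and 2.80. The heat shock gene ATHSP22.0 had the largest total fold in i4g1-2 (10.37) and in 4A-15 (10.30) in the authors' deposited table. eIFiso4G1 was at 0.53 in Col-0, 0.90 in K48M, 0.53 in i4g1-2 and −0.28 in 4A-15 in total mRNA of the authors' deposited table. These folds compare submergence with dark within a line. They do not show the level or the function of eIFiso4G1 in i4g1-2 or 4A-15.

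The polysome columns of the authors' deposited table differ in their centre. Over all models the polysome medians of the authors' deposited table were −0.30 in Col-0, −1.51 in K48M, −0.94 in i4g1-2 and −1.02 in 4A-15, against −0.14, −0.12, −0.09 and −0.08 in total mRNA. After subtraction of these medians the core hypoxia list of the authors' deposited table stood at 4.13, 3.70, 3.99 and 3.83 in polysome RNA, and the starvation list at 1.34, 1.57, 1.30 and 1.31. For K48M polysome RNA the folds in the authors' deposited table lay a median of −1.29 from those of the authors' own test on the count tables (2267 models), while the offset was 0.04 for K48M total, 0.05 for Col-0 total and −0.07 for Col-0 polysome RNA.

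**Figure D4:**
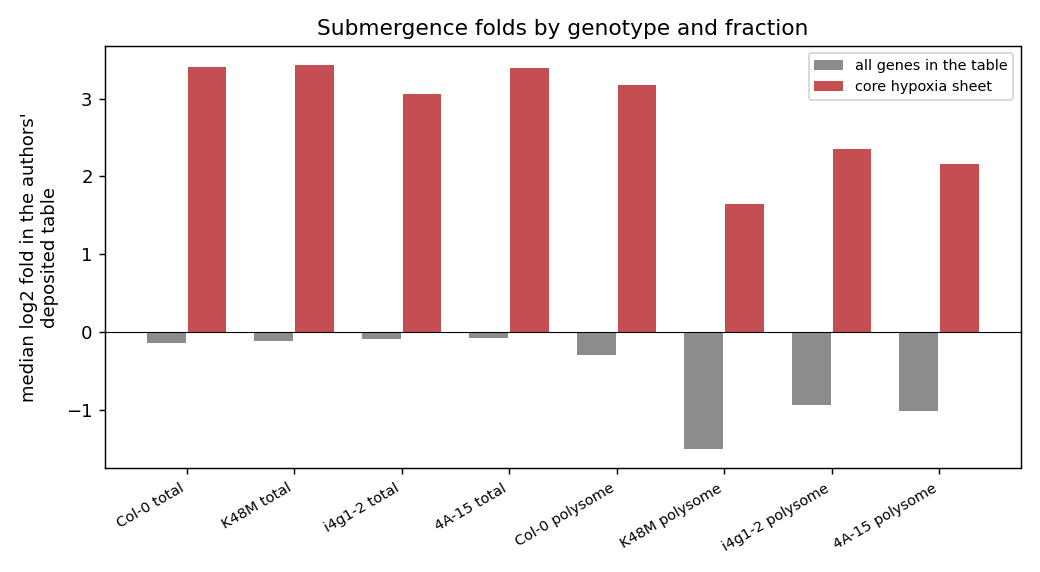
Median log2 fold of submergence against dark in the 8 columns of the authors' deposited table, for all genes (grey) and for the authors' core hypoxia sheet (red). The K48M polysome column lies lowest over all models, at −1.51, and the core hypoxia sheet stands above 0 in each column.

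The authors' list of mRNAs under SnRK1 and eIFiso4G1 holds 130 genes, chosen by the authors partly on these libraries, so its direction is not independent evidence. In polysome RNA of the authors' deposited table its median was 1.72 in Col-0, 0.09 in K48M, 0.62 in i4g1-2 and 0.71 in 4A-15. Fitted here from the counts, the 121 measured genes had a median of 1.54 in Col-0 and 1.29 in K48M polysome RNA, and 87 and 79 of them were called higher. The difference of the responses had a median of −0.21 in the counts, against −1.60 in the authors' deposited table, and −0.03 over all genes in the counts against −1.29 in that table. The value over all genes in the counts is set by the TMM scaling. It therefore cannot show whether fewer mRNAs were on polysomes in K48M. edgeR called 0 of the 121 genes in that difference, 86 had a negative value, and 4 were lower at an unadjusted p under 0.05. For the authors' second list of 955 genes, under SnRK1 without eIFiso4G1, the difference was −0.14 in the counts and −1.55 in the authors' deposited table, with 0 genes called and 13 lower at an unadjusted p under 0.05.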

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

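All explanation tests in this part were chosen only after the results were seen, as were the fits with header or title conditions. ADH1 stood at 1320 CPM in the LTF_GG library titled K48M total dark, against 36.8 ± 12.1 CPM (n = 2) in Col-0 total dark. Crossed titles may account for it: in the direction of the titles this pair ran against the K48M total response of the ST_FR set, with r = −0.66 across 14638 genes, where the Col-0 total responses of the sets correlated with r = 0.70. Crossed column headers are argued against, since in their direction the pair followed the K48M polysome response of its own set with r = 0.80. On the first principal component the library titled dark lay at 40.59 and the one titled submerged at −47.59. The undisputed dark libraries lay between −64.53 and −20.6 there, and the undisputed submerged ones between 24.77 and 63.48. These values argue against the conditions in the titles. Whether the tubes or only the names were exchanged was not tested.

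For organelle genes as a list the camera test at the preset correlation gave an adjusted p of 1.26e-11 for the difference of the polysome responses (0.687 with an estimated correlation) and of 1.46e-13 for the difference of the loading changes (0.953 with an estimated correlation). In the dark their median in polysome RNA was −1.70, and without the first Col-0 polysome dark library, in which ribosomal RNA genes took 38.12% of the gene reads, it was 0.16 with 34 of 89 negative, so that 1 library may carry the difference in the dark. Without it the median difference went from 2.25 to 0.44 for the polysome responses, but only from 3.76 to 1.51 for the loading changes, with 15 of 89 negative, so that library does not account for all of the latter. The total responses are also part of the loading changes. Their organelle median was −1.54 in K48M (77 of 89 negative), from 1 library per condition, and −0.14 in Col-0 (56 of 89 negative). The cause of that lower K48M value was not tested. A difference between the genotypes in the dark stays open, with 1 library per genotype in each set: the list's median, K48M minus Col-0, was 0.04 in the LTF_GG set (43 of 89 negative) and −2.28 in the ST_FR set, which holds the library with much ribosomal RNA (89 of 89 negative).

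Other lists differed in their response between K48M and Col-0 at the preset correlation, and none did with an estimated one. In total mRNA the starvation list had a median difference of 0.33 (adjusted p = 0.015, and 0.758 with an estimated correlation). The heat shock list was at 0.73, or 0.81 without the 1 gene that lacks reads in a group (adjusted p = 8.71e-06, and 0.0913 with an estimated correlation). For hypoxia genes the median was −0.42 (adjusted p = 0.00638, and 0.758 with an estimated correlation) and for photosynthesis genes −0.34, with 22 of 26 negative (adjusted p = 0.00498, and 0.758 with an estimated correlation; 0.13 with the header conditions). Organelle genes in total mRNA were at −1.23 (adjusted p = 0.000789, and 0.817 with an estimated correlation), and with the header conditions the list turned direction (0.874). In polysome RNA the adjusted p was 1.44e-06 for heat shock genes (0.0769 with an estimated correlation) and 9.86e-05 for photosynthesis genes (0.687 with an estimated correlation).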

How the results depend on the processing

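The fits with header or title conditions, on unique gene reads and without ribosomal RNA genes were chosen after the data were seen; the other settings were planned. The K48M total response has 1 library per condition, so no library could be left out there. The cause of the changes below was not tested. Without the replicate block the calls were 471 in Col-0 total, 54 in K48M total, 369 in Col-0 polysome and 509 in K48M polysome RNA; with a block within each fraction K48M total had 2003. With the header conditions they were 1475, 1653, 1212 and 1567 in the same order, and with the title conditions 0 in each. DESeq2 called 1 gene for the difference of the total responses and 13 for total mRNA in the dark, and unique gene reads gave 0 for both comparisons in the dark. With single libraries left out the calls ran from 966 to 3021 in Col-0 total, from 715 to 1182 in Col-0 polysome, from 920 to 1390 in K48M polysome RNA and from 0 to 1 in Col-0 loading. With an estimated correlation 12 list calls were made, against 50 at the preset one. With the header conditions the organelle list turned direction in the difference of the total responses (adjusted p = 0.874), as did the heat shock list in K48M loading (0.0342). With the title conditions these genes turned direction in K48M total mRNA: ADH1 −0.24, SUS4 −0.67, SUS1 −0.64, ACO1 −0.57, ERF71 −1.07, ERF73 −0.08, HSP23.6-MITO −0.30, AT5G10040 −0.29, AT4G10265 −0.66, CYP707A3 −0.33, NRT2:1 −0.12, AT4G11190 0.44, AT2G32220 0.08 and RBCS2B 0.06.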

Other observations

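Tests of explanations in this part were chosen only after the result was seen; the gene lists were planned. Of 12 clock genes 3, 3, 3 and 4 rose in Col-0 total, K48M total, Col-0 polysome and K48M polysome RNA (6, 3, 5 and 4 over the list alone). The camera adjusted p was 0.00564, 0.00152, 0.00213 and 0.00214, but 0.101, 0.0842, 0.0771 and 0.085 with an estimated correlation and 0.102, 0.108, 0.0642 and 0.0685 without the replicate block. Jasmonate and touch genes rose in 5, 1, 2 and 2 of 13 cases (5, 3, 4 and 2 over the list alone; adjusted p = 0.0126, 0.268, 0.004 and 0.0123, and 0.101, 0.461, 0.0771 and 0.085 with an estimated correlation). Of 19 ethylene genes 2, 6 and 4 rose in K48M total, Col-0 polysome and K48M polysome RNA (2, 7 and 4 over the list alone; adjusted p = 0.268, 0.0132 and 0.00408, and 0.71, 0.429 and 0.255 with an estimated correlation). ERF-VII genes rose in 2, 3 and 3 of 5 cases there (adjusted p = 0.0011, 0.000281 and 0.000443, and 0.122, 0.0771 and 0.085 with an estimated correlation). Photosynthesis genes fell in 2, 3 and 5 of 26 cases in Col-0 total, K48M total and Col-0 polysome RNA (2, 6 and 8 over the list alone; medians −0.36, −0.63 and −0.46; adjusted p = 0.00119, 1.56e-06 and 0.000902, and 0.379, 0.301 and 0.456 with an estimated correlation). None of these photosynthesis calls was kept without the replicate block or with the header conditions, where LHCB2.3 in K48M total mRNA went from −2.44 to −1.35. Without that block the clock genes kept 0 calls in each response, jasmonate and touch genes 0, 0, 1 and 1, ethylene genes 1, 2 and 2 and ERF-VII genes 0, 2 and 2, in the orders given.

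Of the 9 SnRK1 complex genes 1, 1, 2 and 3 rose in the 4 responses in the same order (adjusted p = 0.21, 0.977, 0.577 and 0.0453, the last 0.141 with an estimated correlation); in K48M total mRNA their median was −0.26 and their mean 0.02. These calls are AKINBETA1 in Col-0 total, KING1 in K48M total, both in Col-0 polysome, and both with the overexpressed KIN10 itself in K48M polysome RNA. All of them end without the replicate block (adjusted p from 0.186 to 0.403), and with the header conditions all but AKINBETA1 in K48M polysome RNA (0.0803 to 0.167). Unique gene reads end AKINBETA1 in Col-0 total (0.172) and Col-0 polysome RNA (0.399). AKINBETA1 in Col-0 total ends without the first dark (0.32) or the second submerged library (0.15). In polysome RNA each left-out library ends the calls of KING1 and AKINBETA1 in Col-0 (0.0501 to 0.399) and of KIN10 and KING1 in K48M (0.0836 to 0.193), and that of AKINBETA1 in K48M ends with all but the second submerged one (0.0959 to 0.195). Translation initiation genes fell in 1, 0, 1 and 0 of 20 cases in edgeR (0 over the list alone; adjusted p = 0.327, 0.977, 0.739 and 0.514), and both calls end without the block. Root markers had 1 gene up and 2 down of 13 in Col-0 total and 1, 1 and 2 up in the others (adjusted p = 0.0644, 0.268, 0.646 and 0.171), and 0 of these calls were kept without the block. Abscisic acid genes had 1 up in K48M total and 2 up with 2 and 3 down in Col-0 and K48M polysome RNA (adjusted p = 0.705, 0.706 and 0.985); in K48M polysome RNA the median was 0.07, the mean −0.12 and the test's direction up. Without the block 0, 1 and 1 of these abscisic acid calls were kept. The 6 measured ribosomal protein genes of the first list had 2 up in Col-0 total and 1 down in each polysome response (adjusted p = 0.28, 0.268, 0.928 and 0.949; the polysome medians −0.08 and −0.03 stood against a test direction of up), and 0 of these calls were kept without the block. Of the 194 genes of the added list 11 and 1 fell in Col-0 and K48M total mRNA (4 and 1 over the list alone; camera p = 5.68e-07 and 0.000248, and 0.193 and 0.321 with an estimated correlation), and 0 of these calls were kept without the block. Organelle genes had 0 of 89 called in edgeR in total mRNA and in K48M polysome RNA (adjusted p = 0.577, 0.00152 and 0.949, and 0.927, 0.71 and 0.985 with an estimated correlation).

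The translational status sheet of the authors' deposited table holds 537 models, chosen by the authors on these samples. The 20 models marked as raised had a median change of 1.52 in Col-0, −0.90 in K48M, −0.25 in i4g1-2 and −0.32 in 4A-15 in the authors' deposited table. The 517 unmarked models of the authors' deposited table had medians of −1.14, −1.5, −0.93 and −0.90 in the same order. The marked models were picked on Col-0, so lower values in the other lines are no independent evidence, and whether the offsets of the polysome columns enter these scores was not tested. All 24 cytosolic ribosomal protein models of that sheet of the authors' deposited table were lowered in Col-0, with a median of −1.23, where 1 of the 517 unmarked models was raised.

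The K48M polysome folds of the authors' deposited table lie lower than those of the authors' test on the counts, by a median of −1.29 over 2267 models. One factor on the whole column may account for this: the offset was −1.33 in the third of models with the fewest counts and −1.20 in the third with the most, a difference of 0.13. As a factor the offset equals 0.409. Fewer mRNAs on polysomes in submerged K48M, entered by the authors as an outside measurement, could give such a factor, and no measure of polysome amount was used here to decide it. Until then the lower K48M polysome values of the authors' lists in that table cannot be read as specific to those lists.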
